A study of Mus musculus with 4 samples.

How the data were processed

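MeDIP and input DNA of mouse leukaemic cells were measured on 4 Agilent 2-colour arrays, 1 for each of 4 groups: WT or KO cells, without treatment or with 20 nM decitabine every 24 h for 3 days, all harvested at 72 h. Per the labels' protocols, genomic DNA was extracted, methylated DNA was enriched with a commercial kit, part of the starting DNA was kept as input, and both were amplified across the whole genome before labelling. On every array Cy3 was the MeDIP DNA and Cy5 the input DNA, per the labels, so no dyes were swapped and a dye effect cannot be separated from enrichment. Each array came from a different slide and each group lies on a slide of its own, so slide and group cannot be told apart.

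The authors deposited the scanner output of each array, extracted with Agilent Feature Extraction 10.5 per the submitters' processing notes and 10.5.1.1 per the file headers. The deposited intensities of each spot are on a linear scale: per the file headers their background had been subtracted and detrended, surrogate values had replaced signals too close to background, and the dyes had been normalized to each other. The files also hold a log ratio on the log10 scale, Cy5 over Cy3, deposited with each array. The authors' series value table is on a log2 scale: set against the scanner values, 356739 of its 357133 entries with at least 3 non-zero values (99.9%) equal the negative log ratio in log2 units to the decimals given. Its identifiers match no probe column, so this was the only match made, and the alternative called the deposited value table was computed from the scanner log ratio. Its direction is MeDIP over input and it is not centred: 33.3%, 41.3%, 27.8% and 20.7% of its values are exactly 0, and its medians are 0, 0, 0 and -0.14 (WT untreated, KO untreated, WT decitabine, KO decitabine). The alternative was centred on the array median like the others and keeps the zeros of the scanner log ratio.

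From the processed signals the log2 ratio of MeDIP over input was taken per spot, spots of a probe were averaged, and each array was centred on its median with no loess or quantile step. Probes were kept where the input was well above background and neither channel was a non-uniformity outlier on all 4 arrays, which left 328399 of 520554 probes (63.1%). The value of a gene is the mean over the kept probes that the array annotation gives that gene, for genes with at least 3 such probes. Coordinates are those of mm9, the build of the file headers, and all 11253 probe sequences compared with that genome matched it. CpG-dense windows of 500 bp had an observed over expected CpG ratio of at least 0.75 and at least 55% GC, and CpG-poor windows a ratio under 0.48. Gene names are those of the array design and can be old; genes that carry only a sequence identifier as a name are counted but not described. Some genes that met the naming rule are not reported here.

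The MeDIP channel held surrogate values in 66.8%, 66.7%, 51.8% and 50.3% of all spots on the WT untreated, KO untreated, WT decitabine and KO decitabine arrays, and in 60.8%, 58.9%, 38.7% and 37.6% of the kept probes. In comparisons of 2 arrays a named gene is therefore given a size only where at least 1 of its kept probes had MeDIP signal well above background on both arrays. Where this held on 1 array, the ratio was compared with the lowest signal well above background on the other, giving an "at least" fold, and no fold was given where that was under 1 or where neither array had such a probe. Sizes from limma are also given for genes at background on some of the 4 arrays, and the text says which. Sizes still average over dim probes of the same gene, and all folds are open to dye bias.

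Comparisons of 2 arrays counted genes that differed by at least 2-fold with at least 80% of probes moving that way, with no test. Decitabine and genotype were also tested with limma 3.58.1 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05) in an additive model over the 4 arrays. Its 1 residual degree of freedom is the interaction of genotype and treatment, so its errors measure only how far these arrays depart from additivity. Nothing in the labels says whether the arrays came from separate cultures. A gene list was described by the percentile of its median among 10000 random lists of its size, matched on mean log2 ratio and number of probes. The 16 lists held germline, imprinted, housekeeping, HOXA and cofactor, myeloid, stem and progenitor, lymphoid, erythroid and megakaryocyte, non-blood, DNA methylation, H3K4 methylation, decitabine handling, tumour suppressor, interferon response, polycomb and apoptosis genes. Of 436 symbols in them, 406 were found on the array, 18 of these through a synonym. For H19 of the imprinted list the synonym led to Nckap1, another gene, so that list is also given without it.

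The groups, designs, lists, alternative settings and the rule for named genes were chosen before the data were examined. The rule takes, for each comparison of 2 arrays, the 10 largest rises and 10 largest falls among genes with at least 5 kept probes and 80% of probes moving that way, leaving out clone names, predicted loci and receptor families given as groups; 5 and 5 for the difference of effects; the 3 members of each list with the largest change; and Mll5, Hoxa9, Meis1, Dnmt1, Dnmt3a, Dnmt3b and Dck. The alternatives chosen then were normexp with offset 50, loess, scaling to the same median absolute deviation, quantile normalization, centring on housekeeping genes, the deposited value table, no filter, both channels well above background on all 4 arrays, the median over probes, at least 5 probes, the MeDIP channel alone, and limits of 1.5-fold and 4-fold. Added after the data were seen were centring on probes bright in both channels, signals summed over the probes of a gene, probes bright on the arrays compared, and the imprinted list without Nckap1.

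The counting rule and limma were tested on simulated data made from the mean of the 4 arrays over 18332 genes. The same change was added to both decitabine arrays, and the size rule was read for decitabine in WT cells. Of 100 genes changed 2-fold and 100 changed 4-fold, the size rule counted 55 and 100 and limma passed 100 and 100. Of 18102 unchanged genes the size rule counted 9 and limma passed 43. The simulated noise was the departure of the arrays from additivity, an SD of 0.484 over probes and 0.0490 over genes on each array, and real gene changes have an SD of 0.33, so these numbers are optimistic. The simulated changes were exactly additive and the noise was of the kind that limma's errors measure, so limma's counts were largely set by the design. The simulation holds neither background nor surrogate values and says nothing about dim probes. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and R 4.3.3, and figures drawn with matplotlib 3.10.9.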

Results

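DNA methylation was compared in WT and KO mouse leukaemic cells, the latter lacking, by their source names, Mll5, a histone methyltransferase family protein with a SET and a PHD domain, and with and without decitabine, a cytidine analogue that enters DNA and traps DNA methyltransferases. The series asks how MLL5 expression bears on decitabine and on DNA methylation in acute myeloid leukaemia. Methylated DNA was enriched by immunoprecipitation (MeDIP) and hybridised in Cy3 against the input DNA of the same cells in Cy5, on Agilent arrays of mouse promoters and CpG islands. There were 4 groups with 1 array each: WT untreated, KO untreated, WT decitabine and KO decitabine. Treated cells received 20 nM decitabine every 24 h for 3 days and all cells were harvested at 72 h. The genotype field of the KO samples names HOXA9 instead, so the labels disagree on which gene they lack. With no replicate arrays, a difference between 2 arrays has no replicate check and carries no p-value, and an error given after ± for a gene is the SD over its probes.

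MeDIP signal was weak, and brighter on both decitabine arrays. Of 563117 spots that were not controls, the MeDIP channel was well above background in 2.73% (WT untreated), 2.69% (KO untreated), 9.34% (WT decitabine) and 10.7% (KO decitabine), against 83.9%, 74.7%, 80.4% and 69.3% in the input channel. Of 520554 probes, 456158 were not well above background in the MeDIP channel on any of the 4 arrays, 8778 were so on all 4, 22780 only on both decitabine arrays and 8 only on both untreated arrays. The number of arrays and this signal limit the precision of every value that follows. A gene's log2 ratio of MeDIP over input was averaged over its kept probes, of which the median gene of 18332 had 17.

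**Figure D1:**
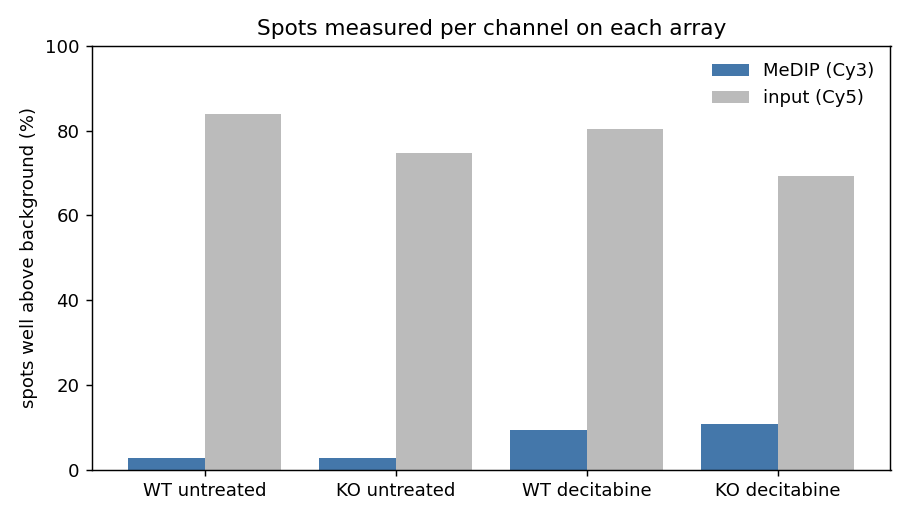
Percentage of spots well above background (vertical axis) in the MeDIP channel (blue) and the input channel (grey) on each of the 4 arrays, 1 bar per array and channel. MeDIP bars stand at 2.73% and 2.69% without decitabine and at 9.34% and 10.7% with it.

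The Mll5 locus (chromosome 5, 22940259 to 23010053, plus strand, mm9) carried no probe named for Mll5, and 17 probes lay within 2000 bp of it. The last ended at 22940709, at the promoter end of the gene, so they check nothing about a deletion elsewhere in it. Their input signal was well above background for 16 probes on the WT untreated, KO untreated and WT decitabine arrays and for 13 on the KO decitabine array. At Hoxa9 (chromosome 6, 52173099 to 52181088, minus strand), a homeobox gene that drives myeloid leukaemia, the input of 50, 43, 49 and 39 of 57 probes was well above background on the WT untreated, KO untreated, WT decitabine and KO decitabine arrays. Their median input signal stood above that of the array by 0.33, 0.30, 0.21 and 0.16, which argues against a loss of most of the probed Hoxa9 sequence in KO cells; a deletion of a small part is not excluded, and Mll5 cannot be checked. Germline genes, whose CpG-rich promoters are methylated in somatic cells, had a higher median log2 ratio than housekeeping genes with unmethylated islands on every array, by 0.21 ± 0.13, 0.33 ± 0.15, 0.22 ± 0.10 and 0.31 ± 0.09 (bootstrap SD over 26 germline and 30 housekeeping genes) in the same order. With the median over probes in place of the mean, the difference on the WT untreated array turned to -0.08. The share of probes with MeDIP signal well above background was lower for germline than for housekeeping genes on 3 arrays (4.21% and 5.45%, 3.77% and 4.91%, 15.1% and 15.3%) and higher on the KO decitabine array (18.6% and 16.4%), so the enrichment is not seen in this measure. The ratio also falls with CpG density (medians of -1.61 at CpG-dense and -0.50 at CpG-poor probes on the WT untreated array), and olfactory receptor genes lay above germline genes on both untreated arrays (-0.18 against -0.66 in WT, -0.43 against -0.53 in KO cells). A difference between lists is therefore no proof of enrichment.

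In WT cells, decitabine was compared with no treatment to see which promoters changed. Ly6g6c, a lymphocyte antigen 6 family gene, had a log2 ratio 1.73 higher with decitabine (3.31-fold, 15 probes, chromosome 17, 35203834 to 35206636, 5 exonic and 10 intronic), and its probes with MeDIP signal well above background went from 1 to 9. Zbtb4, a zinc finger protein that binds methylated DNA, was 1.61 ± 1.29 higher (3.06-fold, 10 probes, chromosome 11, 69577972 to 69580944, of which 7 intronic). Dynlt1, a dynein light chain, was 1.58 ± 0.83 higher over 7 intronic probes (chromosome 17, 6432788 to 6435784), and Tmem181, a transmembrane protein, 1.49 ± 1.28 higher over 14 probes (chromosome 17, 6298844 to 6313721). Pik3r4, Psors1c2, D5Ertd579e, Ezh1 and Syt5 were also among the 10 largest rises but had MeDIP signal well above background with decitabine only. For D5Ertd579e (chromosome 5, probes at 37086702 to 37087563) the ratio was at least 1.09-fold higher; the bound for Pik3r4, Psors1c2, Ezh1 and Syt5 was under 1, so no fold is given. Of the 10 largest falls, Phkb, a phosphorylase kinase subunit, was lower by a log2 change of -0.75 ± 0.82 over 5 probes (chromosome 8, 88365470 to 88367183, each with the same sign). On each array only 1 of the 5 probes had MeDIP signal well above background. Cyp2c37, Col3a1, C6 and Cysltr1 had no probe with MeDIP signal well above background on either array, and no fold is given for them.

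Imprinted genes and lymphoid genes stood apart from other genes in this comparison. The median of 26 genes of the imprinted list was 0.44 higher with decitabine, at percentile 99.6 of 10000 random lists matched on ratio and probe number, and 23 of the 26 were above 0. Nckap1 entered this list through a synonym that it shares with H19 and is not the imprinted gene; without it the median of 25 was 0.42 (percentile 99.4). Examples are Snrpn (0.74 ± 1.03, 23 probes) and Dlk1 (0.70 ± 0.85, 34 probes). The median of 27 lymphoid genes was 0.49 higher, at percentile 99.98, and 23 were above 0, among them Klrb1c (0.76 ± 0.97), Cd4 (0.70 ± 0.83) and Cd22 (0.70 ± 0.74). With summed signals, which measured 18 of the 27, the lymphoid list lay inside the central 95%. No member of either list passed the 2-fold limit. Dnmt3l, a cofactor of de novo methylation, was 1.11 ± 1.05 higher over 27 probes, and Tex11, a meiosis gene of the germline list, 1.01 ± 0.80 higher over 14; the medians of their lists lay inside the central 95%. Hoxa9 was 0.31 ± 0.90 higher, Dnmt1 0.46 ± 0.94 and Dnmt3a 0.37 ± 1.18. Centring on bright probes, which lowers every gene by 0.60 here, turns Hoxa9, Dnmt1 and Dnmt3a below 0, with Hoxa9 at -0.29 and Dnmt1 at -0.14. The other genes named in this paragraph stay above 0. It also turns the medians of the imprinted and lymphoid lists below 0, but leaves their percentiles unchanged.

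In WT cells, 250 genes were higher and 4 lower with decitabine by at least 2-fold with at least 80% of probes moving that way. Of the 250, 92 had a probe with MeDIP signal well above background on both arrays, 142 on 1 of them and 16 on neither. The direction of these counts depends on where an array is centred. The median gene change was 0.25, and 98.4% of the counted genes were higher; centred on the housekeeping list the counts were 53 higher and 51 lower, with loess 28 and 48, and centred on the probes bright in both channels on all 4 arrays 17 and 386, which lowers every gene by 0.60. Among 816 genes with at least 3 probes bright on both arrays, 149 were higher and 0 lower before such centring.

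In KO cells the same comparison was made. D5Ertd579e was 1.65 ± 1.21 higher with decitabine (3.14-fold, 5 probes), Acbd7, an acyl-CoA binding protein, 1.53 ± 1.10 (2.89-fold, 6 probes, chromosome 2, 3252023 to 3254478), Ncoa3, a nuclear receptor coactivator, 1.45 ± 0.62 (2.74-fold, 6 probes, chromosome 2, 165818066 to 165818989, of which 5 intronic), and Ccdc64, a coiled-coil protein, 1.38 ± 0.86 (2.60-fold, 13 probes, chromosome 5, 116112574 to 116182922). Nlgn1, a synaptic adhesion molecule, was among the largest rises with MeDIP signal well above background with decitabine only; its bound was under 1 and no fold is given. Of the 10 largest falls, 9 had no probe with MeDIP signal well above background on either array, among them Il2, Ccr3, Clca2, Prl2b1 and Flt4. Ncoa3 turned to -0.76 when signals were summed over probes.

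Housekeeping genes with CpG islands were 0.38 higher in the median with decitabine in KO cells (percentile 98.9, 23 of 30 above 0, for example Polr2a at 0.66 ± 0.98). Genes of the interferon response were 0.03 higher in the median, at percentile 0.38 of random lists whose own median was 0.21, and 15 of 28 were above 0. The interferon list came inside the central 95% with loess (percentile 6.46), with no filter (4.92), in the MeDIP channel alone (20.4) and with summed signals (11.9, over 11 of the 28 genes). Ifit3, an interferon-induced gene, was 0.78 ± 0.95 higher over 4 probes. Centring on bright probes lowers every gene by 0.87 here, which turns Ifit3 and the list medians of this paragraph below 0. Genes of the imprinted list were 0.31 higher in the median (percentile 94.9, or 87.5 without Nckap1) and lymphoid genes 0.23 (percentile 61.5), both inside the central 95%. Dnmt3l was 0.81 ± 0.93 higher. The housekeeping list left the upper 2.5% with loess (percentile 51.7), quantile normalization (96.7) and the MeDIP channel alone (32.0), and lay at percentile 2.41 when signals were summed over probes. Summed signals measured only 21 of its 30 members.

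In KO cells, 209 genes were higher and 2 lower with decitabine, of which 87 of the 209 had MeDIP signal well above background on both arrays. Centred on bright probes, which lowers every gene by 0.87, 5 were higher and 2345 lower; with loess 7 and 23, and from the deposited log ratios 41 and 39. Among 994 genes with at least 3 probes bright on both arrays, 432 were higher and 0 lower. Changes in WT and KO cells, which share no array, correlated across genes at r = 0.60, where genes are not independent replicates. 60 genes were counted higher in both, against 2.85 for independent lists, and 0 were counted in opposite directions. Independence is no fair expectation here, since in both genotypes the untreated array held more surrogate MeDIP values than the decitabine array. Their shares of kept probes were 60.8% against 38.7% in WT and 58.9% against 37.6% in KO cells. The correlation and the overlap therefore do not show a repeated response to decitabine.

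**Figure D2:**
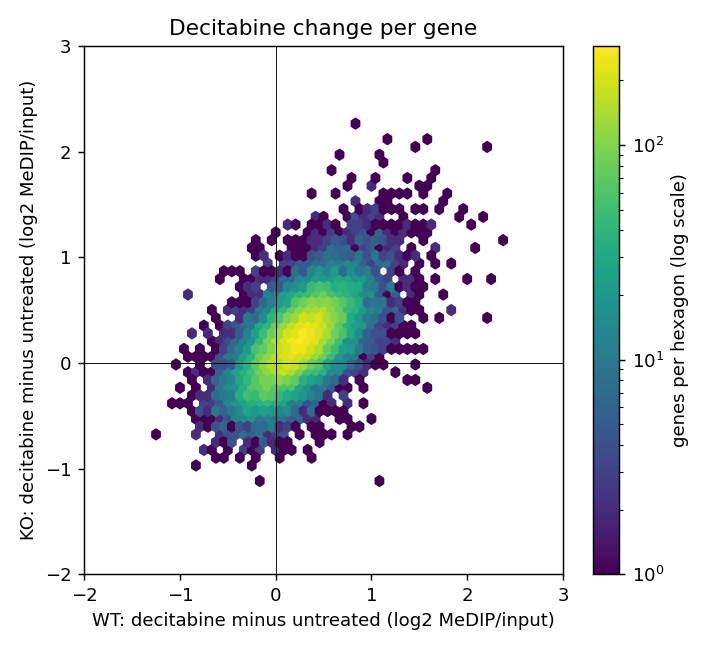
Change in log2 MeDIP over input with decitabine per gene, in WT cells (horizontal axis) and KO cells (vertical axis), for 18332 genes; colour gives the number of genes per hexagon on a log scale. The cloud is centred at 0.25 and 0.21 and follows the diagonal (r = 0.60).

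Assuming that genotype and treatment effects add, limma could test decitabine over all 4 arrays, with 1 residual degree of freedom. Its errors are small where the changes in WT and KO cells were alike. Since both untreated arrays held more surrogate MeDIP values, neither this likeness nor a small adjusted p shows a repeated response to decitabine. D5Ertd579e rose by 1.58 (SE 0.12, limma adjusted p = 0.000348), Acbd7 by 1.35 (SE 0.13, adjusted p = 0.000672) and Phkb fell by 0.68 (SE 0.12, adjusted p = 0.00549). Dnmt3a rose by 0.42 (adjusted p = 0.0286), while Hoxa9 at 0.33 (adjusted p = 0.0605), Dnmt1 at 0.32 (adjusted p = 0.0842), Meis1 at 0.09 (adjusted p = 0.595), Dnmt3b at 0.10 (adjusted p = 0.541) and Dck, the kinase that activates decitabine, at -0.22 (adjusted p = 0.185) did not pass. D5Ertd579e, Dck and Dnmt3b had MeDIP signal well above background on some of the 4 arrays only, so their sizes rest partly on dim probes. The other genes had such signal on every array, but their sizes also average over dim probes. Phkb had it at 1 of its 5 probes on each array. On the WT untreated, KO untreated, WT decitabine and KO decitabine arrays, Hoxa9 had it at 1, 1, 4 and 3 of 28 probes. In the same order Dnmt1 had it at 1, 2, 4 and 4 of 18, and Dnmt3a at 2, 1, 8 and 8 of 30.

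In the same limma model 5777 of all 18332 genes passed, and the counts of each list are to be read against that share. The tumour suppressor, decitabine handling, DNA methylation, interferon and polycomb lists lay below it. Whether any list differed from it was not tested. Members of each list that passed over all genes, and then adjusted over the list alone, were as follows. Genes of the imprinted list passed in 14 of 26 cases and 17 adjusted over the list alone (13 of 25 and 16 without Nckap1), lymphoid genes in 14 of 27 and 14, and housekeeping genes in 13 of 30 and 18. Stem and progenitor genes passed in 11 of 25 and 16, myeloid differentiation genes in 11 of 31 and 11, and germline genes in 10 of 26 and 11. Tumour suppressors passed in 10 of 36 and 10, HOXA genes with their cofactors in 7 of 17 and 10, H3K4 methylation enzymes in 8 of 17 and 9, and apoptosis genes in 7 of 21 and 8. Markers of tissues outside the blood passed in 8 of 20 and 8, erythroid and megakaryocyte genes in 6 of 17 and 6, interferon response genes in 7 of 28 and 6, and DNA methylation enzymes in 5 of 17 and 5. Genes of decitabine transport and metabolism passed in 5 of 18 and 1, and polycomb-bound developmental genes in 7 of 38 and 3. Of the members that passed over all genes, 1 was lower in each of the stem and progenitor, erythroid, non-blood, interferon and polycomb lists, and the others were higher.

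Over all genes, 5777 of 18332 passed limma for decitabine, 5459 higher and 318 lower. Centred on bright probes the count was 10111, of which 74 higher and 10037 lower, and with loess it was 255, of which 53 higher, so neither the number nor the direction is fixed by these data.

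KO and WT cells were compared without treatment to see what differed with genotype. Zfp827, a zinc finger protein, was 1.19 ± 0.70 higher in KO cells (2.28-fold, 8 intronic probes, chromosome 8, 81553538 to 81636710), and Zbtb4 1.14 ± 0.71 higher (2.21-fold, 10 probes). Galntl1 and Shc2 had MeDIP signal well above background in KO cells only, with bounds under 1, and Ankrd44, Igfbp7, Mcpt4, Arfgef1 and Snx10 in neither. Zfp75 was lower by a log2 change of -0.91 ± 0.92 over 15 intergenic probes (chromosome 9, 19425021 to 19428573), with 1 probe well above background on each array. Hist2h2bb, a histone gene, Zranb3, Wdr53, Anapc4, Tmem188, Mrgprb3 and H2-T10 were among the largest falls with no such probe on either array. Dnmt3l was 0.84 ± 0.60 higher in KO cells and Gata2, a stem cell transcription factor, 0.69 higher over 52 probes. Zbtb4 and Dnmt3l were also higher with decitabine in WT cells. That comparison shares the WT untreated array with this one, so their values in both are not independent.

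Housekeeping genes were lower in untreated KO cells relative to matched genes: their median was -0.08 against 0.13 for random lists (percentile 0 of 10000, 9 of 30 above 0), with Tbp at -0.49 ± 0.85 and Ywhaz at 0.67 ± 0.74. Lymphoid genes were higher, by 0.27 in the median (percentile 99.9, 18 of 27 above 0), with Cd22 at 0.49 ± 0.57 and Cd4 at 0.40 ± 0.77. This comparison and that of decitabine in WT cells share the WT untreated array, so the lymphoid values in both are not independent. It shares the KO untreated array, with opposite sign, with the comparison of decitabine in KO cells. The low housekeeping value here and the high one there are therefore not independent either. Genes of the imprinted list were 0.19 higher (percentile 96.3, or 91.6 without Nckap1), inside the central 95%. The housekeeping list moved to percentile 19.2 with normexp, 31.1 in the MeDIP channel alone and 18.5 with summed signals, and the lymphoid list to 82.4 with loess, 94.1 with the median over probes and 44.0 in the MeDIP channel alone.

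Without treatment, 60 genes were higher and 17 lower in KO cells, and of the 60, 10 had MeDIP signal well above background on both arrays and 45 on neither. The input channel carried 56.8% of the variance of these gene changes, against 10.8% for decitabine in WT cells, 23.8% in KO cells and 61.2% for genotype under decitabine. With loess 12 were higher and 50 lower. In the MeDIP channel alone 11 genes were counted, and 5 of them were among the 77 counted here.

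Under decitabine, KO and WT cells were compared in the same way. Galntl1, a polypeptide N-acetylgalactosaminyltransferase family gene, was 1.77 ± 1.24 higher in KO cells (3.41-fold, 6 probes, chromosome 12, 81619771 to 81620791), Nlgn1 1.37 ± 1.49 (2.58-fold, 7 exonic probes, chromosome 3, 26230237 to 26230958) and Slc4a11, a membrane transporter, 1.28 ± 1.02 (2.43-fold, 5 probes, chromosome 2, 130522606 to 130523274). Tns3, Cdc2l5, Arhgef16, Spna2 and the microRNA locus mmu-mir-804 were higher by 1.13, 1.13, 1.13, 1.11 and 1.10, with MeDIP signal well above background on both arrays. Nlgn1 was also among the largest rises with decitabine in KO cells, a comparison that shares the KO decitabine array, so both are not independent. Zfp75 was lower by a log2 change of -0.93 ± 0.73 and Vbp1, a prefoldin subunit, by a log2 change of -0.90 ± 1.03 over 16 probes (chromosome X, 72756173 to 72760684). In the MeDIP channel alone Zfp75 did not fall in this comparison, so its lower ratio lies in the input channel. Cd200r2, Sult1b1, Ccnk, Hist1h4f, Prl7c1 and Hist2h2bb had no probe well above background on either array.

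Developmental genes bound by polycomb had a median 0.21 higher in KO cells under decitabine (percentile 99.3, 33 of 38 above 0), with Pax2 at 0.56 ± 0.66, Lhx5 at 0.42 ± 0.72 and Olig2 at 0.36 ± 0.73. Among random lists matched instead on GC content and CpG density of the probes, a matching chosen after the data were seen, this list lay at percentile 79.8. It also came inside the central 95% with normexp (88.2), in the MeDIP channel alone (40.9) and with summed signals (63.9). No other list left the central 95%: housekeeping genes lay at -0.03 (percentile 4.13), lymphoid genes at -0.02 (percentile 14.5) and the interferon response at 0.06 (percentile 67.5).

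Under decitabine 96 genes were higher and 12 lower in KO cells, and 63 of the 96 had MeDIP signal well above background on both arrays. In the MeDIP channel alone 18 genes were counted, and 4 of them were among these 108. Centred on bright probes, 23 were higher and 111 lower; among 6007 genes with at least 3 bright probes, 146 were higher and 5 lower. Genotype differences with and without decitabine correlated across genes at r = 0.50, with most of their variance in the input channel (56.8% without and 61.2% with decitabine). 9 genes were higher in KO cells in both, against 0.314 for independent lists, and 4 were lower in both, against 0.0111. Both differences also rose with CpG density, so independence is no fair expectation for these counts.

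In the additive limma model, Galntl1 rose in KO cells by 1.39 (SE 0.17, limma adjusted p = 0.00750), D5Ertd579e by 0.97 (SE 0.12, adjusted p = 0.00750) and Tns3 by 0.99 (SE 0.13, adjusted p = 0.00750), and Zfp75 fell by 0.92 (SE 0.12, adjusted p = 0.00778). Galntl1 and D5Ertd579e had no probe well above background in the MeDIP channel on the WT untreated array and Tns3 on neither untreated array, so these sizes rest partly on dim probes, as does that of Dnmt3b. Most probes of Hoxa9, Meis1, Dnmt1 and Dnmt3a were also dim on every array. Zfp75 had MeDIP signal well above background at 1 of its 15 probes on each array. In the MeDIP channel alone it did not fall between genotypes under decitabine. Small errors in this model mean only that genotype differences were alike with and without decitabine, with most of their variance in the input channel. Hoxa9 at 0.26 (adjusted p = 0.232), Meis1 at 0.09 (adjusted p = 0.673), Dnmt1 at 0.13 (adjusted p = 0.575), Dnmt3a at 0.30 (adjusted p = 0.174) and Dnmt3b at 0.29 (adjusted p = 0.193) did not pass. Of the 16 lists, 6 had a single member that passed over all genes: Dnmt3l (0.69, limma adjusted p = 0.0234), Cebpd, a myeloid transcription factor (0.60, adjusted p = 0.0285), Hoxa7 (0.60, adjusted p = 0.0422), Dck (-0.61, adjusted p = 0.0282), Brca1 (-0.61, adjusted p = 0.0331) and the beta globin Hbb-b2, which was lower. These members, apart from Dck, were named after their values were seen, and Hbb-b2, given no size, had no probe well above background in the MeDIP channel on any array. Hoxa7, Cebpd and Brca1 had such probes only with decitabine, and Dck only on the WT untreated and KO decitabine arrays. Adjusted over the list alone, the stem and progenitor list had 2 and each of these 6 lists 1. In all, 749 genes passed limma, 543 higher and 206 lower, from 6 with arrays scaled to the same median absolute deviation to 2725 with no filter on probes.

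**Figure D3:**
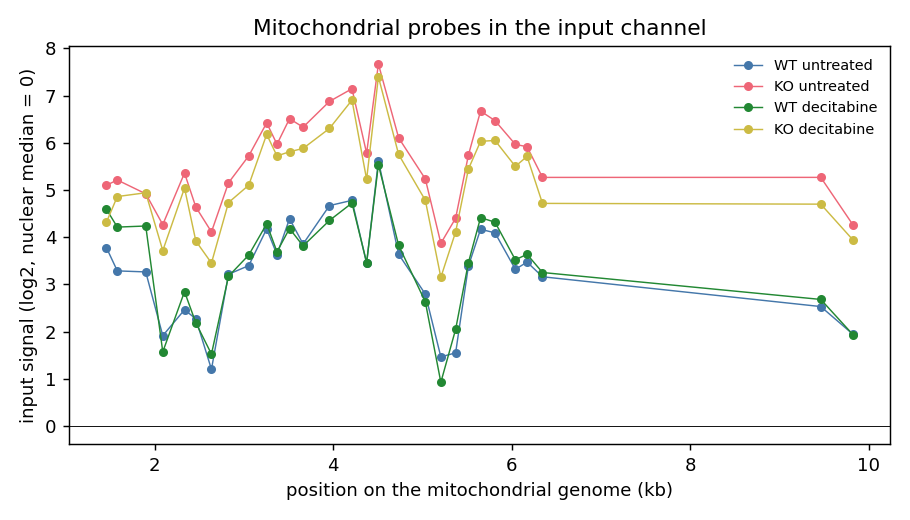
Log2 input signal of 29 mitochondrial probes above the nuclear median (vertical axis) by position on the mitochondrial genome in kb (horizontal axis), 1 colour per array. Medians are 3.39 (WT untreated), 5.72 (KO untreated), 3.62 (WT decitabine) and 5.10 (KO decitabine).

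**Figure D4:**
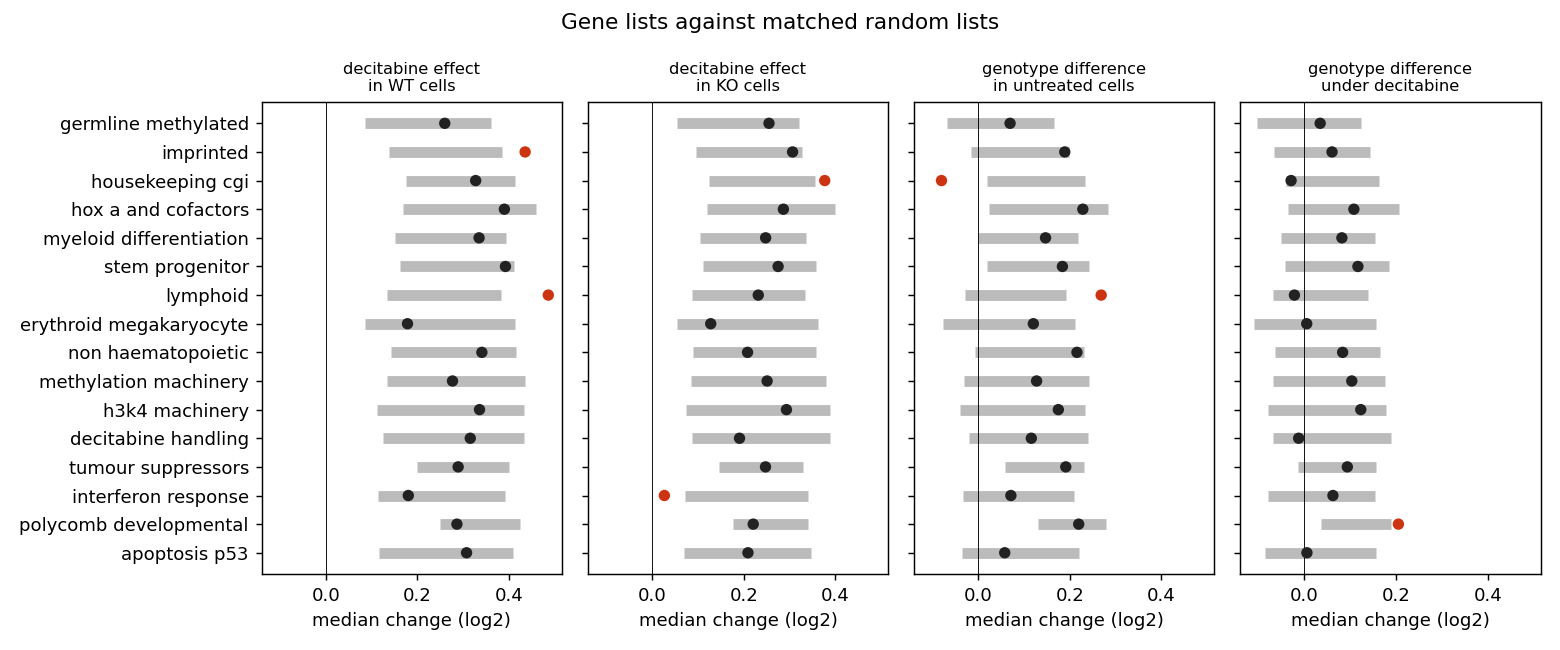
Median log2 change of each of 16 gene lists (points, horizontal axis) in the 4 comparisons of 2 arrays, over grey bars for the central 95% of 10000 matched random lists; red points lie outside. Lymphoid genes lie above the bar at 0.49 for decitabine in WT cells and at 0.27 for genotype in untreated cells.

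The difference of the decitabine effects asks whether KO cells responded otherwise than WT cells; with 1 array per group it has no test. Ly6g6c, with MeDIP signal well above background on all 4 arrays, had a difference of -1.29 ± 1.16, its rise being larger in WT cells. Igfbp7, Pik3r4 and Myo1a differed the same way and H2-T10, Vpreb1, Arfgef2, Fau and Atp7b the other way, each with MeDIP signal on some arrays only. Lymphoid genes had a median difference of -0.16 (percentile 1.93 of matched random lists), with Cd8a at -0.68 ± 1.03, Cd79b at -0.59 ± 1.01 and Klrb1c at -0.57 ± 1.02. Of the 10 other settings that do not move all genes alike, 3 kept the lymphoid list in the lowest 2.5%: it lay at 22.4 with loess, 16.1 with the median over probes, 15.3 with quantile normalization and 14.1 in the MeDIP channel alone, and at 11.4 among lists matched on GC content and CpG density. Germline genes lay at percentile 4.84, DNA methylation enzymes at 3.81 and markers of tissues outside the blood at 2.51, inside the central 95%. Of 18332 genes, 32 had a higher and 47 a lower difference by at least 2-fold, and changes from odd and even probes of the same gene correlated across genes at only r = 0.0869, against 0.263, 0.261, 0.345 and 0.313 in the comparisons of decitabine in WT, decitabine in KO, genotype untreated and genotype under decitabine.

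Across the 16 lists and 5 comparisons, 8 of 80 list medians lay outside the central 95% of matched random lists, where 4 would by chance. The comparisons share arrays, so these medians are not separate draws, and each lymphoid median outside rests on the WT untreated array. With matching on GC content and CpG density, 6 of these 8 stayed outside, and the imprinted list between untreated genotypes (percentile 97.8, but 92.7 without Nckap1) and polycomb-bound genes with decitabine in KO cells (percentile 1.40) came to lie outside. Along the genome, probes in CpG-dense windows changed more than those in CpG-poor windows: the median ratio was 0.25 against 0.08 higher with decitabine in WT cells, 0.52 against 0.02 in KO cells, 0.40 against 0.06 in KO over WT cells untreated, and 0.52 against -0.04 under decitabine. The input channel itself differed at CpG-dense probes, by -0.49 in the last of these, by -0.24 with decitabine in KO cells and by -0.21 between untreated genotypes, against 0.09, 0.06 and 0.03 at CpG-poor ones. MeDIP signal was well above background at 4.19% (WT untreated) to 21.8% (KO decitabine) of CpG-dense probes. At CpG-poor probes the share was 3.76% (KO untreated) to 15.1% (KO decitabine). The median ratios of both classes therefore rest mostly on dim probes and do not show a change of methylation in CpG-dense windows. No autosome stood apart in input DNA, with chromosome medians between -0.06 and 0.07 in every comparison.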

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

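All tests of the mitochondrial probes were chosen only after the result was seen.

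The arrays carry 29 probes of the mitochondrial genome that the gene comparisons do not use, and their input signal differed between genotypes. In untreated cells it was 5.11-fold higher in KO than in WT cells (log2 difference 2.35, quartiles over probes 2.21 and 2.47, 29 of 29 probes higher). Under decitabine it was 3.91-fold higher (log2 1.97, quartiles 1.66 and 2.10, 28 of 29 probes higher). Above the nuclear median, mitochondrial input stood at a log2 of 3.39 on the WT untreated, 5.72 on the KO untreated, 3.62 on the WT decitabine and 5.10 on the KO decitabine array. With decitabine it changed by 0.08 in WT cells and by -0.43 in KO cells. These values stood out as signal in data outside the comparisons, above the level in WT cells.

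For a stretched range of bright probes, random sets were drawn from the 3000 brightest nuclear probes within the GC range of the mitochondrial probes. Of 10000 sets, 0 reached the difference in either treatment. These probes were not matched in brightness: only 667 nuclear probes on the KO untreated and 760 on the KO decitabine array lay between the mitochondrial quartiles of input signal. The sets therefore do not cover that brightness well, and a stretched range stays open. Amplification of the input alone is argued against: the MeDIP channel of the same probes was higher in KO cells by 1.42 without and 1.17 with decitabine. The lower quartiles over probes were 0.52 and 0.88. Both the MeDIP and the input DNA were amplified, so these values cannot test unequal amplification in both channels, which stays open. Also open is whether mitochondrial DNA was carried over unequally when the DNA was prepared, not held by the cells. With 1 preparation per group this and the genotype cannot be told apart. A higher mitochondrial DNA content of the KO cells may therefore be a hypothesis for a measurement on separate preparations, and no test here bears on it directly.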

How the results depend on the processing

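The settings with bright probes as centre, summed signals and probes bright on the arrays compared, the matching on GC content and the imprinted list without Nckap1 were chosen only after the results were seen.

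Of 827 values for the 90 largest rises and falls, such as Phkb and Zfp75, 781 held, 41 moved and 5 turned in settings that do not move all genes alike, which large changes favour. Those that turned were Ncoa3 with decitabine in KO cells (-0.76 with summed signals), Flt4 in the same comparison (0.0775 with normexp), Vpreb1 in the difference of effects (-0.34 with normexp), and, between genotypes under decitabine in the MeDIP channel alone, Zfp75 (0.0017) and Hist2h2bb (0.0393). Of 81 values for the 8 gene lists outside the central 95%, from the same settings, 56 held, 24 were weaker and 1 turned, the housekeeping list with decitabine in KO cells (percentile 2.41 with summed signals). The number of lists outside was 8 of 80, against 14 with no filter, 15 with the median over probes and 3 with the MeDIP channel alone. The difference of germline over housekeeping genes turned on the WT untreated array with the median over probes (-0.0846, from 0.21), was 0.37 there with no filter, and was 0.13 on the KO decitabine array with normexp (from 0.31).

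Counts of genes depended on the setting, and the cause was not tested. They were 254 for decitabine in WT (250 higher), 211 for decitabine in KO (209 higher), 77 for untreated genotype (60 higher) and 108 for genotype under decitabine (96 higher). The difference of effects gave 79 (32 higher), limma decitabine 5777 (5459 higher) and limma genotype 749 (543 higher). Only counts that moved by over 1.5 times, or by 10 points in their share of higher genes, follow.

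Normexp gave 116 for decitabine in WT (116 higher), 66 for decitabine in KO (64 higher), 152 for untreated genotype (146 higher), 37 for genotype under decitabine (37 higher). It gave 53 for the difference (5 higher), 3790 for limma decitabine (3745 higher), 2315 for limma genotype (2266 higher). Loess gave 76 for decitabine in WT (28 higher), 30 for decitabine in KO (7 higher), 62 for untreated genotype (12 higher), 50 for genotype under decitabine (19 higher). It gave 119 for the difference (54 higher), 255 for limma decitabine (53 higher), 175 for limma genotype (32 higher). Equal median absolute deviation gave 96 for decitabine in WT (93 higher), 27 for untreated genotype (10 higher), 126 for genotype under decitabine (94 higher). It gave 91 for the difference (54 higher), 2432 for limma decitabine (2150 higher), 6 for limma genotype (1 higher). Quantile normalization gave 63 for decitabine in WT (49 higher), 154 for decitabine in KO (137 higher), 29 for untreated genotype (10 higher), 155 for genotype under decitabine (120 higher). It gave 124 for the difference (88 higher), 1265 for limma decitabine (949 higher), 152 for limma genotype (68 higher).

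Centring on the housekeeping genes gave 104 for decitabine in WT (53 higher), 95 for decitabine in KO (64 higher), 79 for the difference (40 higher). It gave 2833 for limma decitabine (969 higher), 1195 for limma genotype (870 higher). The deposited log ratios gave 80 for decitabine in KO (41 higher), 183 for untreated genotype (177 higher), 75 for genotype under decitabine (54 higher). It gave 273 for the difference (6 higher), 268 for limma decitabine (257 higher), 189 for limma genotype (173 higher). Without a filter the counts were 87 for decitabine in WT (78 higher), 112 for decitabine in KO (104 higher), 56 for the difference (32 higher). It gave 2984 for limma decitabine (2289 higher), 2725 for limma genotype (1469 higher). With both channels well above background on all 4 arrays, which left 424 genes, the counts were 135 for decitabine in WT, 5 for untreated genotype, 5 for genotype under decitabine. It gave 4 for the difference, 384 for limma decitabine, 77 for limma genotype.

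The median over probes gave 128 for untreated genotype (93 higher), 163 for genotype under decitabine (137 higher), 156 for the difference (55 higher). It gave 1023 for limma decitabine (977 higher), 48 for limma genotype (39 higher). Genes with at least 5 probes gave 114 for decitabine in KO, 30 for untreated genotype, 38 for genotype under decitabine, 35 for the difference. The MeDIP channel alone gave 733 for decitabine in WT, 547 for decitabine in KO, all higher, 11 for untreated genotype (10 higher), 18 for genotype under decitabine (13 higher). It gave 52 for the difference (20 higher), 15304 for limma decitabine (15292 higher), 126 for limma genotype (98 higher). At 1.5-fold the counts were 849 for decitabine in WT, 824 for decitabine in KO, 690 for untreated genotype. It gave 632 for genotype under decitabine, 436 for the difference.

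At 4-fold the counts were 7 for decitabine in WT, 5 for decitabine in KO, 0 for untreated genotype. It gave 0 for genotype under decitabine, 1 for the difference. Centring on bright probes gave 403 for decitabine in WT (17 higher), 2350 for decitabine in KO (5 higher), 134 for genotype under decitabine (23 higher). It gave 215 for the difference (6 higher), 10111 for limma decitabine (74 higher), 238 for limma genotype (93 higher). Summed signals gave 96 for decitabine in WT (63 higher), 27 for decitabine in KO (16 higher), 20 for genotype under decitabine (5 higher). It gave 50 for the difference (8 higher), 1119 for limma decitabine (537 higher), 146 for limma genotype (58 higher). Probes bright on the arrays compared gave 149 for decitabine in WT, 432 for decitabine in KO, 5 for untreated genotype, 4 for the difference.

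The median of all genes moved with the scaling. With decitabine in WT cells it was 0.25, against 0.49 in the MeDIP channel alone, 0.78 with both channels bright, -0.09 with loess, 0.13 with equal median absolute deviation, 0.03 with quantile normalization, -0.05 centred on housekeeping genes and -0.35 centred on bright probes. With decitabine in KO cells it was 0.21, against 0.50 in the MeDIP channel alone, 0.92 with both channels bright, -0.10 with loess, 0.09 with quantile normalization, -0.05 centred on housekeeping genes, -0.09 from the deposited log ratios, -0.01 with summed signals and -0.66 centred on bright probes. Between untreated genotypes it was 0.09, against 0.28 with normexp, -0.10 with loess, -0.01 with equal median absolute deviation, -0.04 with quantile normalization, 0.19 with both channels bright and 0.29 from the deposited log ratios. Between genotypes under decitabine it was 0.04, against 0.12 with normexp, 0.07 centred on housekeeping genes, 0.28 with both channels bright, -0.12 with loess, -0.02 with summed signals, -0.07 from the deposited log ratios and -0.26 centred on bright probes. The difference of effects was -0.05, against -0.15 with normexp, 0.11 with both channels bright, -0.35 from the deposited log ratios and -0.32 centred on bright probes; it was above 0 with quantile normalization (0.05), equal median absolute deviation (0.01), the MeDIP channel alone (0.0053) and housekeeping genes as centre (0.0028).

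With both channels well above background on all 4 arrays no list kept 5 members, so no list or germline value exists under it. Turning the sign of the ratio, set for germline genes below housekeeping genes, was not needed. No paired analysis was possible because the groups share 1 replicate number only; the additive model does compare treatments within genotypes.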

Other observations

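The tests of the brighter MeDIP channel, and the tests of olfactory receptors by single comparison, were chosen only after the results were seen; base composition and the input channel over all 4 comparisons were set down before.

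Olfactory receptor genes, which detect odorants and lie in large AT-rich clusters, had a lower change in ratio than matched genes in every comparison of 2 arrays. The median of 790 genes was -0.15 with decitabine in WT cells, -0.17 in KO cells, -0.21 between untreated genotypes and -0.26 between genotypes under decitabine, each at percentile 0 of 10000 lists matched on ratio and probe number (random medians 0.16, 0.14, -0.00 and -0.04). The direction of the medians is not fixed: with normexp they were 0.00, -0.02, -0.01 and -0.07, with the MeDIP channel alone 0.15, 0.22, -0.07 and -0.00, and from the deposited log ratios 0.00 between untreated genotypes. Vomeronasal receptors, 99 genes for pheromone detection, had medians of -0.23, -0.26, -0.24 and -0.29 in the same order. Their direction also turned with the MeDIP channel alone with decitabine (0.11 and 0.17) and from the deposited log ratios between untreated genotypes (0.02).

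The low changes in ratio of olfactory receptors could come from the base composition of their probes, whose median GC content was 36.8% against 49.5% for all genes. Against lists matched on GC content and CpG density, the highest percentile over the 4 comparisons was 26.2, so over all of them this stays open. With decitabine in WT cells they stayed low (percentile 0.45), but the lists matched on GC content and CpG density had a median of -0.11, near the -0.15 of the receptors. Lists matched on ratio and probe number had 0.16 there, so base composition may account for much of the gap. The matching was in bins, so whether it accounts for all of the gap stays open. In the 3 other comparisons the receptors lay at percentile 3.39 or above, where base composition may suffice. With the MeDIP channel alone they lay at percentile 0 in 3 comparisons, which argues against the input channel alone, and at 72.2 between genotypes under decitabine, where the input channel alone may account for them; over all 4 comparisons its highest percentile, 72.2, leaves it open. No biological explanation was tested.

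MeDIP signal was brighter on both decitabine arrays, though decitabine traps the enzymes that methylate DNA. Before dye normalization the median MeDIP signal over spots, background subtracted, went from 7.85 to 21.2 in WT cells and from 17.8 to 18.9 in KO cells. Dye normalization then scaled this channel by a factor of 14.8 (WT untreated), 8.99 (WT decitabine), 7.88 (KO untreated) and 10.2 (KO decitabine). The sizes that follow include these factors, so their likeness in both genotypes depends on the scaling. Among probes well above background in both channels on all 4 arrays, MeDIP signal was higher with decitabine by a log2 of 0.62 in WT cells (78.7% of probes higher) and 0.64 in KO cells (92.4%). A brighter MeDIP channel as a whole may explain this, through the pull-down, amplification or labelling; the difference was larger at CpG-dense than at CpG-poor probes by up to 0.461 (0.95 against 0.49 in WT cells, 0.83 against 0.57 in KO cells), which a gain common to all probes would not give, but a gain that varies with signal could, so it stays open. Decitabine itself cannot be told apart from it: 2 of 2 decitabine arrays had a higher share of bright probes than both untreated arrays, and each group has 1 preparation. The gene changes with decitabine are therefore relative to each array's centre and do not say whether total methylation went up or down.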
